A study of Mus musculus with 6 samples.

How the data were processed

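The series compared hematopoietic stem cells (HSC), the bone marrow cells from which all blood lineages arise, of wild-type (WT) mice with HSC of mice lacking Selp (Selp-/-), the gene of the adhesion receptor P-selectin. The labels give C57BL/6 as the strain of both genotypes. There were 6 arrays, 3 per genotype, each numbered 1 to 3 within its genotype in the labels. Total RNA was amplified and labelled with biotin for 1-colour hybridization, per the labels' protocols. How the HSC were sorted is not given in the sources used here. Nothing in the labels says that the arrays of a genotype came from separate mice, so p-values measure only the spread between these samples, which may be technical.

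The deposited values are linear probe set intensities on an Affymetrix whole-transcript mouse array, 28815 probe sets per array. MAS5 is named, with no version, per the submitters' processing notes. The deposited intensities were all multiples of 0.5, and their medians ran from 563 in WT 2 to 751 in WT 3. Their lowest values ran from 43 to 55. No scaling to a common level and no background subtraction was therefore visible in them, and the scale factor of MAS5, if any was applied, stays unknown. No column of the table lacked a sample. The arrays give no depth as read counts do, and their number limits the precision.

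The planned processing, fixed before the data were examined, took scaled MAS5 values as log2(value + 16) with no further normalization. Since the deposited intensities were unscaled, the intensities were instead corrected for background with normexp and an offset of 50, put on the log2 scale and quantile normalized across the 6 arrays, all in limma 3.58.1 under R 4.3.3. That change was made from the unit of the values, before any comparison was fitted, and the planned processing was run as an alternative. Probe sets below the 40th percentile of the mean log2 level over the 6 arrays were left out, which left 17289 probe sets. Each was fitted with genotype as the term of the model (lmFit, then eBayes with a trend of variance on level), two-sided, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Fold changes are differences of log2 levels, Selp-/- minus WT.

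Gene names came from the platform's annotation, updated through gene identifiers in a RefSeq table of the mouse assembly GRCm38.p6. Of the 28815 probe sets, 21780 had 1 gene symbol, 1605 several and 5430 none, and 21689 of those with 1 symbol matched a RefSeq gene. Only probe sets with 1 symbol were named. No probe set carried the name Selp, alone or among several symbols, so the level of the deleted gene was not analysed here and the genotype labels were not checked by it. The deposited values name no genome build, so the RefSeq table served only for names and for which genes lie near Selp.

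The genes named in the text follow a rule fixed before the data were examined. It takes Selp, then the 12 genes higher and the 12 lower in Selp-/- with the largest change among those past the threshold and with no overlap between genotypes. Where fewer pass, the places go to the smallest unadjusted p in that direction. The rule further takes up to 4 genes of each gene list by smallest p, of which at most 2 are named here except where a test singles out another, and Actb and Gapdh. Gapdh had no tested probe set with that symbol alone. Clone names were passed over. Genes and probe sets outside the rule are said to have been chosen after their values were seen.

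The 26 gene lists were fixed before the data were examined, 16 of pathways and 10 of cell types that a sort could hold. The pathway lists covered HSC self-renewal and identity, S phase, G2 and M phase, cell cycle inhibitors and quiescence, adhesion and homing, Wnt, Notch, TGF-beta and BMP signalling, the interferon response, NF-kB and inflammatory signalling, immediate early genes, apoptosis and p53 targets, oxidative phosphorylation, glycolysis and hypoxia, cytosolic ribosomal proteins, and arachidonate and lipid mediators. The cell type lists held markers of erythroid, megakaryocyte, neutrophil, monocyte, dendritic, B lymphoid, T and NK lymphoid, mast cell, endothelial and stromal cells. Lists with at least 5 tested members were tested with camera at the preset correlation of 0.01, on the brightest probe set of each of 12455 genes, with an estimated correlation and fry beside it. Genes within 10 Mb of Selp were compared with all other tested genes by a two-sided Fisher's exact test of their share among the 200 genes of smallest p, the planned substitute where fewer than 20 genes pass the threshold.

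Arrays with the same number were checked for pairing by correlating their deviations from the genotype means across probe sets. The correlations were 0.43 for the arrays numbered 1, 0.53 for those numbered 2 and 0.81 for those numbered 3, so the numbers were taken to pair the samples. Arrays with different numbers also deviated together, with 0.51 between WT 2 and Selp-/- 1, while WT 3 and Selp-/- 1 gave -0.63. Levels correlated across probe sets at 0.973 between WT 3 and Selp-/- 3 and at 0.866 between WT 2 and WT 3. No pair of arrays held the same values, the highest share of identical intensities being 0.493%. The fit with the replicate number as a block was run as an alternative. Other alternatives planned in advance were pseudocounts of 1 and 64, no filter or one at the 60th percentile, other scalings, other variance models, array weights, 1 probe set per gene, other thresholds and list tests, windows of 2 and 20 Mb, and leaving out each array. A block for the arrays numbered 3, the arrays numbered 1 and 2 alone, and a window of 100 places in the gene order were chosen after seeing the data. The pseudocount settings were run with quantile normalization and no background correction.

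The fits were tested on simulated data for the comparison of Selp-/- with WT over 17289 probe sets, with the arrays' own replicate differences and spread and 200 seeded changes. Without the block, 0 of 67 changes of 0.5 on the log2 scale, 22 of 67 of 1 and 57 of 66 of 2 were recovered, with 0 false calls. With the block, 42 of 67, 67 of 67 and 66 of 66 were recovered, with 19 false calls. With 200 changes seeded, the adjustment is laxer than where few probe sets change, so these shares may overstate recovery in the real data. There, with the block, probe set 10351206 gave a log2 fold change of -2.04 and an adjusted p of 0.124 (limma). In a simulation of the list test over 26 lists, a list shifted by 0.3 passed the threshold and 0 others did. That shift was larger than the means of the lists that passed in the real data (0.12 and 0.18). Splits of the real arrays other than the genotypes, with the replicate block, gave 8, 10 and 6 lists. The simulation is therefore no measure of false list calls in these data. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.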

Results

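Expression was measured on 6 mouse arrays, 3 from WT HSC and 3 from Selp-/- HSC, to ask which genes P-selectin controls in these cells. P-selectin is an adhesion receptor known from platelets and endothelium, where it lets white blood cells roll on the vessel wall. The median intensity was 636, 563 and 751 in WT 1, WT 2 and WT 3, and 701, 638 and 713 in Selp-/- 1, Selp-/- 2 and Selp-/- 3. The level of Selp itself was not analysed here, since no probe set in the annotation used carried its name.

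Arrays of the same number had close expression profiles in the 2 genotypes, with levels correlating at 0.970, 0.970 and 0.973. No named gene stood beyond the spread of its genotype's arrays after correction for multiple testing. The fit without the replicate block had little power for moderate changes. In simulated data it recovered 0 of 67 changes of 0.5 and 22 of 67 of 1 on the log2 scale. Among the genes of smallest p, Rbbp7, a histone-binding subunit of chromatin complexes, measured 11.14 ± 0.11 in WT and 11.76 ± 0.06 in Selp-/- HSC (log2 level, SD, n = 3), a ratio of 1.54. Mid1, a microtubule-associated ubiquitin ligase, measured 10.87 ± 0.63 and 9.43 ± 0.11, or 2.71 times more in WT. Gas5, a non-coding host transcript of small nucleolar RNAs, measured 11.29 ± 0.57 and 10.25 ± 0.37, or 2.06 times more in WT. Ppox, an enzyme of heme synthesis, measured 10.58 ± 0.11 and 10.03 ± 0.15.

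The test with limma called 0 of 17289 probe sets higher and 0 lower in Selp-/- HSC at an adjusted p of 0.05, the lowest adjusted p being 1. At an unadjusted p under 0.05 there were 122 probe sets, 74 higher and 48 lower. By chance 864 would be expected if the 6 arrays varied independently. Arrays paired by number do not, so the 122 cannot be read against that count. The 3 values of a genotype lay wholly above or below those of the other for 728 probe sets, 4.21% of those tested, against 10% by chance if the 6 arrays were exchangeable, which arrays paired by number are not. With the replicate number as a block, 0 and 0 passed (lowest adjusted p 0.124) and 630 lay under an unadjusted 0.05. In the arrays numbered 1 and 2 alone, an alternative chosen after seeing the data, 0 probe sets were called higher and 4 lower, namely Mid1 and 3 probe sets with no gene name.

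None of the following genes passed the threshold, and the SE given are from the fit without the replicate block. On the higher side in Selp-/- HSC, Marchf5, a ubiquitin ligase of the outer mitochondrial membrane, gave a log2 fold change of 0.65 (SE 0.16). Cdk5r1, the activator of the kinase Cdk5, gave 0.36 (SE 0.09). The deubiquitinase Usp12 gave 0.41 (SE 0.10), and the translation initiation subunit Eif3m gave 0.46 (SE 0.14). H2ac4, a histone gene of a family of near-identical copies and so uncertain, gave 0.47 (SE 0.14). Cd48, a surface protein of the SLAM family used to tell HSC from later progenitors, measured 10.73 ± 0.29 in WT and 11.25 ± 0.07 in Selp-/- HSC (SD, n = 3). Parp11, Tmem65, Tox4, Dip2c and Xpnpep3 gave 0.33, 0.40, 0.43, 0.39 and 0.34.

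On the lower side, Igkv4-91, a variable segment of the immunoglobulin kappa chain, gave -1.33 (SE 0.31). That segment belongs to a multigene family whose probes can share sequence, so its value is uncertain. Nit1 gave -0.36 (SE 0.12), the carbonic anhydrase Car7 -0.30 (SE 0.09), and Iars2, the mitochondrial isoleucine tRNA ligase, -0.33 (SE 0.13). Bnipl, Nkx1-2, Ghrl, Sdccag8 and Krtap5-4 lay between -0.31 and -0.25. Actb, a housekeeping gene, gave 0.01 (SE 0.05), and turned to -0.13 when the unscaled arrays were centred on their medians and to -0.15 relative to all probe sets without normalization.

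**Figure D1:**
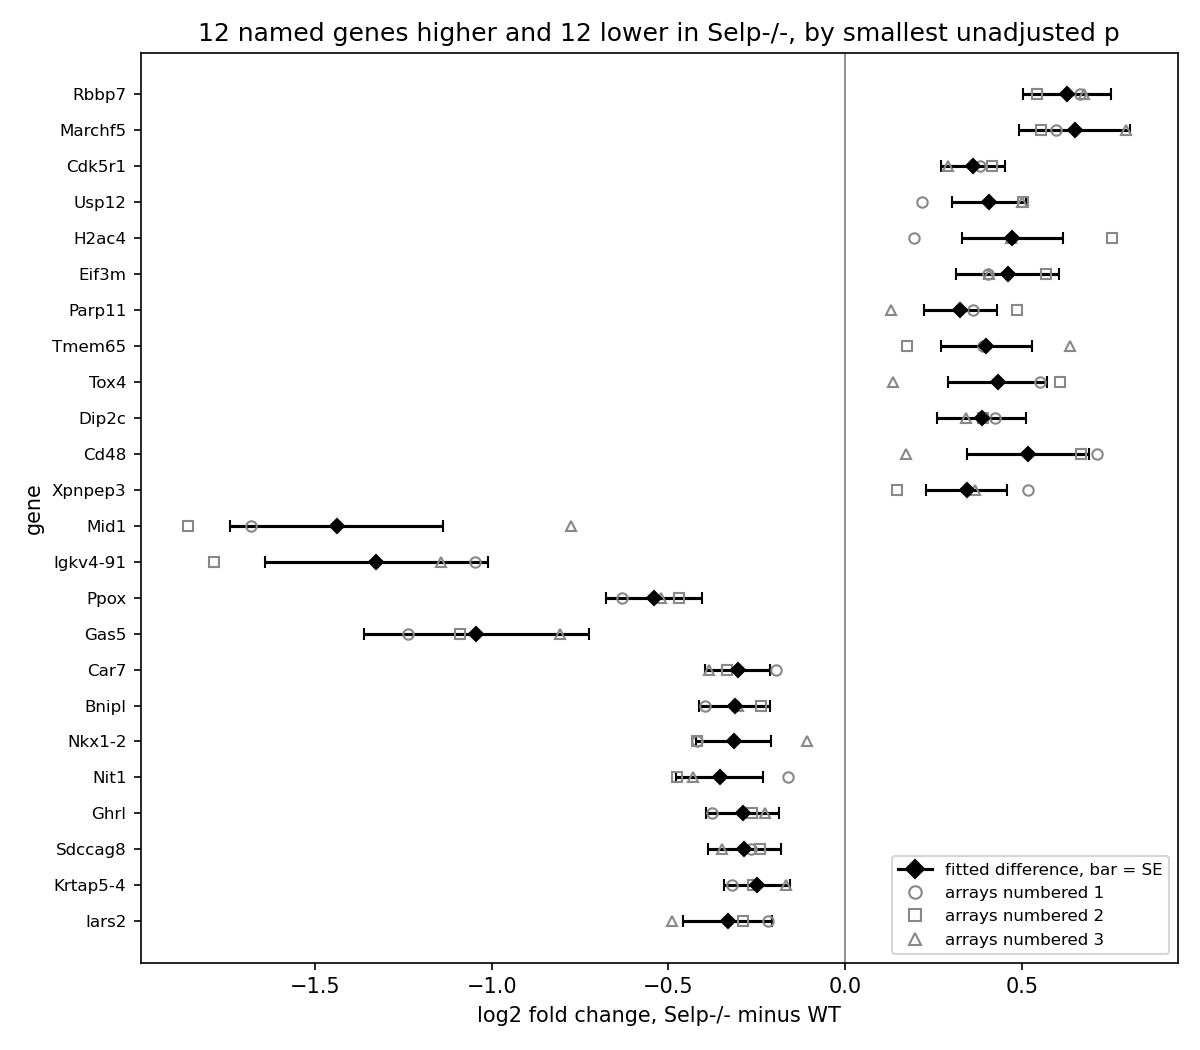
Log2 fold change (Selp-/- minus WT) of the 12 named genes higher and the 12 lower in Selp-/- HSC by smallest unadjusted p, each with its fitted value and SE (diamond and bar, 3 arrays per genotype) and the difference within each replicate number (open symbols). The fitted values run from -1.44 for Mid1 to 0.65 for Marchf5, and 0 of the genes passed the adjusted threshold.

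The 3 probe sets of smallest p had no gene symbol in the annotation, and were chosen after their values were seen. Probe set 10351206 gave a log2 fold change of -2.04 (SE 0.31), 4.11 times more in WT. Probe set 10351197 measured 12.32 ± 0.37 in WT and 10.79 ± 0.34 in Selp-/- HSC (log2, SD, n = 3), 2.90 times more in WT. Probe set 10539574 measured 11.24 ± 0.01 and 11.88 ± 0.08. Their adjusted p from limma was 1 each, and 0.124, 0.739 and 0.739 with the replicate block.

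Among gene groups, 2 of the 26 lists passed the test at a preset correlation, both higher in mean in Selp-/- HSC, and neither passed with an estimated correlation (camera, p = 0.305 and 0.436). Genes of oxidative phosphorylation, the respiratory chain and ATP synthase of mitochondria, had a mean difference of 0.12 on the log2 scale (SE over genes 0.018), with 42 of the 49 measured genes above 0. Cox5b, a subunit of cytochrome c oxidase, measured 11.39 ± 0.25 in WT and 11.86 ± 0.25 in Selp-/- HSC (SD, n = 3), and Atp5d, a subunit of ATP synthase, 12.84 ± 0.32 and 13.18 ± 0.06. The interferon response list, genes induced by antiviral signalling, had a mean difference of 0.18 (SE over genes 0.039), with 27 of 30 above 0. Ifit2 measured 8.60 ± 0.26 and 9.28 ± 0.70, and Rsad2 9.02 ± 0.18 and 9.56 ± 0.81.

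The adjusted p of camera was 0.00069 for oxidative phosphorylation and 0.0439 for the interferon response. With an estimated correlation the adjusted p of camera was 0.992 for each, and fry called 0 lists. Of the genes of either list, 0 passed when adjusted over the list alone and 0 over all genes tested. The oxidative phosphorylation call was lost without WT 2 (mean 0.027, adjusted p 0.813) and without Selp-/- 3 (mean 0.028, adjusted p 0.738). The interferon call was lost without WT 1 (mean 0.11, adjusted p 0.248) and without WT 2 (mean 0.13, adjusted p 0.364), and without Selp-/- 3 the list passed in the other direction (mean -0.094, adjusted p 0.0285). Leaving out 1 array breaks a pair and sets the remaining array of that number against the others, so these values mix genotype with replicate number.

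The difference in the interferon list lay mainly in the arrays numbered 3. It was -0.0056 between the arrays numbered 1, 0.063 between those numbered 2 and 0.49 between those numbered 3. The monocyte list, which did not pass, differed alike, by -0.027, 0.084 and 0.46. Selp-/- 3 also stood apart in Xist, the transcript of the inactive X, at an intensity of 398 against 5010 in WT 3. For oxidative phosphorylation the differences were 0.049, 0.14 and 0.17. Within the arrays numbered 1 and 2 alone the mean was 0.092 for oxidative phosphorylation and 0.029 for the interferon response, with an adjusted p of 0.0957 and 0.982.

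**Figure D2:**
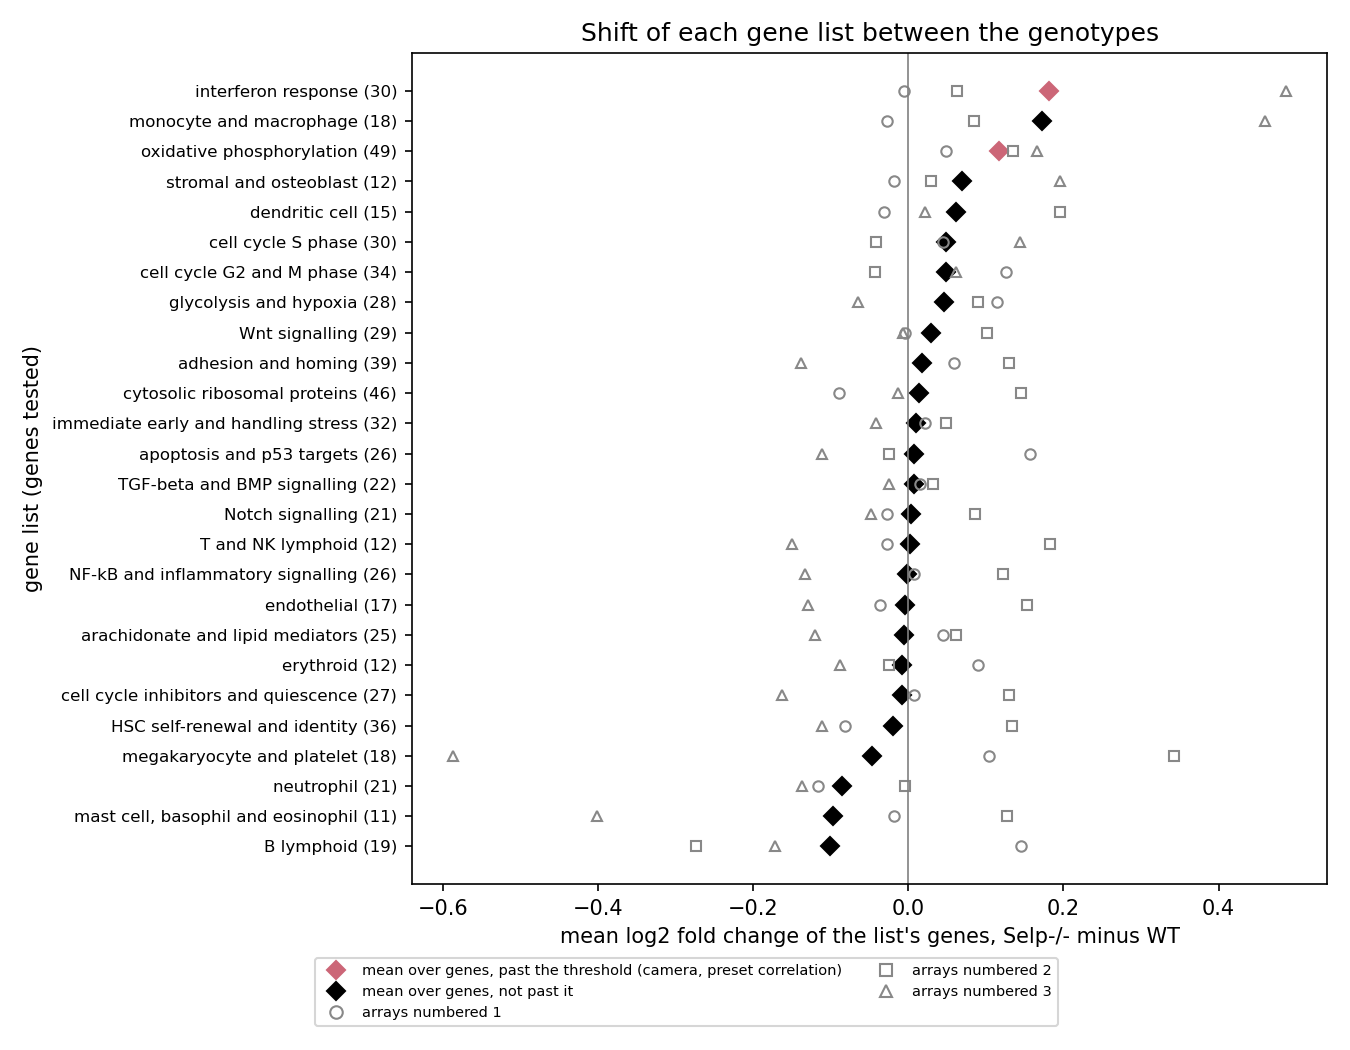
Mean log2 fold change (Selp-/- minus WT) over the tested genes of each of the 26 gene lists (diamonds, the number of genes in brackets) and the mean difference within each replicate number (open symbols). The interferon response (0.18) and oxidative phosphorylation (0.12) passed the threshold of camera with the preset correlation but not with an estimated one (adjusted p 0.992 each), and the interferon difference is 0.49 in the arrays numbered 3 and near 0 in those numbered 1.

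The lists that describe HSC did not pass the test. The 36 measured genes of HSC self-renewal and identity had a mean of -0.020, with 15 above 0 and 21 below, and Slamf1, the HSC marker CD150, measured 9.26 ± 0.16 in WT and 9.58 ± 0.73 in Selp-/- HSC (SD, n = 3). Abcb1a, a drug efflux pump, gave -0.14 (SE 0.14). Of 39 genes of adhesion and homing, 20 lay above 0 and 19 below, with a mean of 0.017 and values of 0.35 (SE 0.24) for Vcam1 and 0.28 (SE 0.19) for Alcam. The cell cycle lists had means of 0.049 over 30 genes of S phase, 0.048 over 34 genes of G2 and M phase and -0.0085 over 27 inhibitors. Cdt1, which licenses replication origins, gave 0.19 (SE 0.14), and Cdc20, an activator of the anaphase-promoting complex, gave 0.22 (SE 0.20).

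Of the signalling lists, Wnt had a mean of 0.030, Notch of 0.0035, TGF-beta and BMP of 0.0069 and NF-kB of -0.0014. Immediate early genes had a mean of 0.0096, apoptosis and p53 targets of 0.0072, glycolysis and hypoxia of 0.046, cytosolic ribosomal proteins of 0.014 and lipid mediators of -0.0050. Ptges, the prostaglandin E synthase, gave 0.36 (SE 0.13). Median, mean and test differed in sign for 4 lists, which were apoptosis, cell cycle inhibitors, immediate early genes and TGF-beta.

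Markers of other blood cells did not pass either. The means were 0.17 for 18 monocyte genes, 0.062 for 15 dendritic genes, 0.069 for 12 stromal genes and 0.0018 for 12 T and NK genes. They were -0.10 for 19 B lymphoid genes, -0.097 for 11 mast cell genes, -0.086 for 21 neutrophil genes, -0.047 for 18 megakaryocyte genes, -0.0076 for 12 erythroid genes and -0.0041 for 17 endothelial genes. Irf8, a transcription factor of monocytes and dendritic cells, measured 10.54 ± 0.29 in WT and 10.91 ± 0.16 in Selp-/- HSC, and Cd79a, a part of the B cell receptor, 10.41 ± 0.40 and 9.77 ± 0.56 (SD, n = 3). The lowest adjusted p of camera among the 24 lists was 0.378. With the replicate block, 1 gene of any list passed when adjusted over the list alone, Cxcr2 of the neutrophil list. Its log2 fold change was -0.78, with an SE of 0.14 with the block and 1.25 without it.

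Genes near Selp were compared with the rest of the genome, since a targeted allele can carry flanking sequence from the cells in which it was made. Of the 118 tested genes within 10 Mb of Selp, 5 were among the 200 genes of smallest p, against 200 of 12455 genes overall. They were Gas5, Ppox, Nit1 and Zfp648, lower in mean in Selp-/- HSC, and Cd48, higher in mean. With the replicate block there were 9, adding Cd84, Olfml2b and Dcaf8 with log2 fold changes of -0.47, -0.50 and -0.32, and Ufc1 and Ralgps2 with 0.38 and 0.39, while Zfp648 was not among them. Those near genes outside the 24 above were chosen after their values were seen.

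Fisher's exact test gave an odds ratio of 2.75 (95% interval 0.868 to 6.73, p = 0.0415) without the block, and 5.25 (2.30 to 10.5, p = 0.000117) with it. The test takes genes as independent, which neighbouring genes may not be. Within 2 Mb, 0 of 22 tested genes were among the 200. Probe sets without a gene name, 10351206 and 10351197 among them, were outside all of these counts. By the same exact test a window of 20 Mb gave 1.99 (p = 0.135) without the block and 3.45 (p = 0.00116) with it, and one of 100 places in the gene order 1.46 (p = 0.502) in both. Without normalization, as first planned, the 10 Mb window gave 2.17 (exact p = 0.122), past the threshold no longer.

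**Figure D3:**
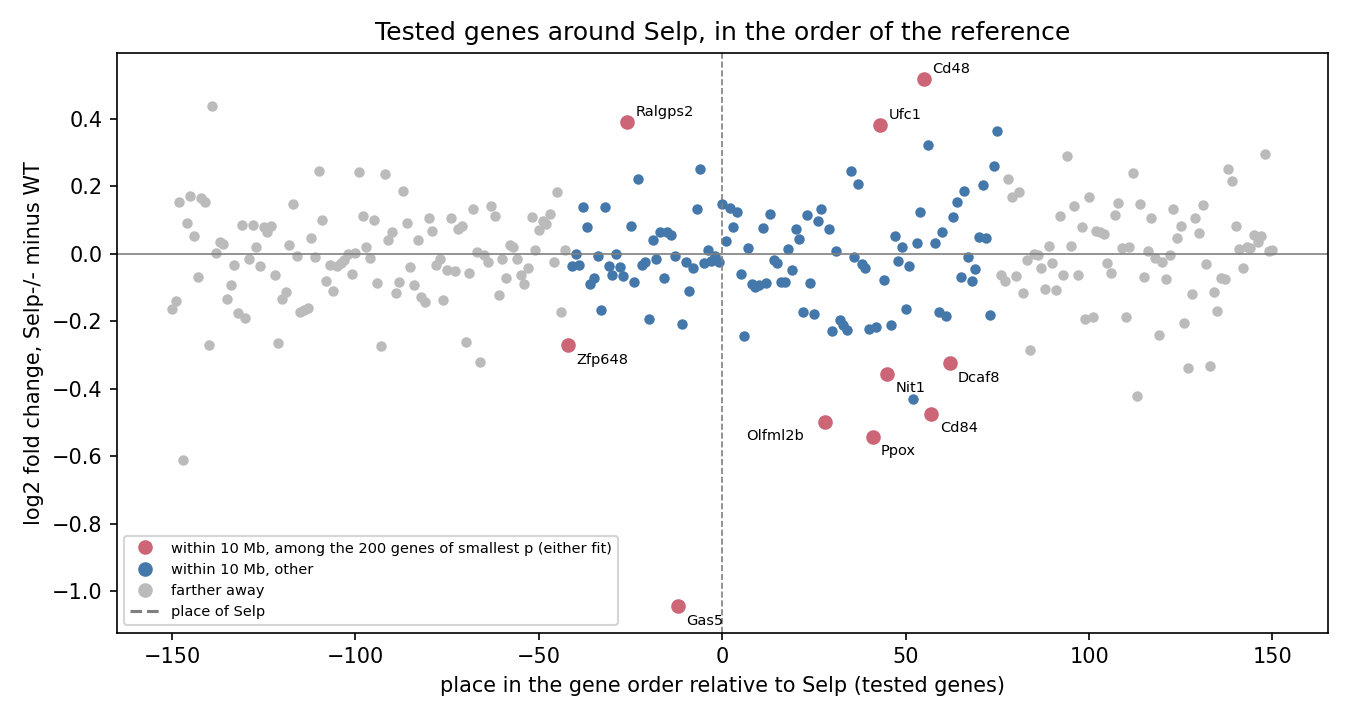
Log2 fold change (Selp-/- minus WT) of each tested gene around Selp, placed by its order in the mouse reference GRCm38.p6 and not by distance, with 1 probe set per gene. Red points are the near genes among the 200 of smallest p with or without the replicate block, from Gas5 at -1.04 to Cd48 at 0.52, blue points are other genes within 10 Mb and grey points lie farther away.

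The largest differences among the 6 arrays followed the replicate number and not the genotype. HSC genes lay lower in the arrays numbered 3 of both genotypes than in the other 4 arrays, and mast cell, basophil, neutrophil and monocyte genes lay higher. Hlf, a transcription factor of HSC, measured 12.45, 12.37 and 8.88 in WT 1, WT 2 and WT 3, and 12.13, 12.53 and 8.81 in Selp-/- 1, Selp-/- 2 and Selp-/- 3. In WT 3 and Selp-/- 3 Hlf was thus near 8.79, the mean level under which probe sets were left out. Mecom lay under it there, at 8.16 and 8.01, while Kit stayed at 10.58 and 11.11. The labels call all 6 arrays HSC, but every comparison with n = 3 includes this pair of unlike profile. Mcpt8, a basophil protease, measured 9.38, 9.65 and 14.16 in the WT arrays and 9.60, 9.57 and 13.95 in the Selp-/- arrays. The mast cell enzyme Cpa3 measured 10.58, 10.18 and 14.00 in WT and 10.10, 10.63 and 13.59 in Selp-/- HSC.

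Of 36 HSC genes, 7 lay higher in WT 3 than in the mean of WT 1 and WT 2, and 4 in Selp-/- 3 by the same measure, against 10 and 9 of 11 mast cell genes, 17 and 19 of 21 neutrophil genes and 13 and 16 of 18 monocyte genes. The NF-kB list lay 0.70 higher in WT 3 and 0.50 higher in Selp-/- 3 by the same measure, and the immediate early list, which responds to handling, 0.34 and 0.26 higher. Megakaryocyte genes lay 1.08 and 0.27 higher, T and NK genes 0.77 and 0.54 higher, and erythroid genes at -0.78 and -0.90. The genes named for this pattern were chosen after their values were seen. Angpt1, Flt3, Meis1 and Mecom of the HSC list measured 9.30, 9.57, 9.95 and 8.16 in WT 3, against 11.66, 12.14, 11.48 and 10.10 in WT 1. The neutrophil chemokine receptor Cxcr2 measured 9.21, 8.57 and 12.55 in WT and 8.77, 7.82 and 11.41 in Selp-/- HSC. The macrophage marker Adgre1 measured 8.13, 8.22 and 11.95 in WT and 7.93, 8.36 and 11.49 in Selp-/- HSC. The carbonic anhydrase Car1, an erythroid gene, differed between the arrays numbered 1 and 2 as well, with 14.01, 12.08 and 9.08 in WT and 13.95, 11.91 and 9.14 in Selp-/- HSC.

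Relative to the mean of the 6 arrays, the HSC list lay at 0.22, 0.30 and -0.50 in WT 1 to 3 and at 0.14, 0.44 and -0.61 in Selp-/- 1 to 3. The mast cell list lay at -0.64, -0.65 and 1.44 in WT and at -0.66, -0.52 and 1.03 in Selp-/- HSC, and the neutrophil list at 0.11, -1.07 and 1.09 and at -0.0059, -1.08 and 0.95. The interferon list lay at 0.15 in WT 3 and 0.64 in Selp-/- 3, and below 0 in the other 4 arrays. The first principal component held 68.0% of the variance and separated the arrays numbered 3 from the rest. A term for the replicate number was past an adjusted p of 0.05 (limma) for 2217 probe sets, 12.8% of those tested.

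**Figure D4:**
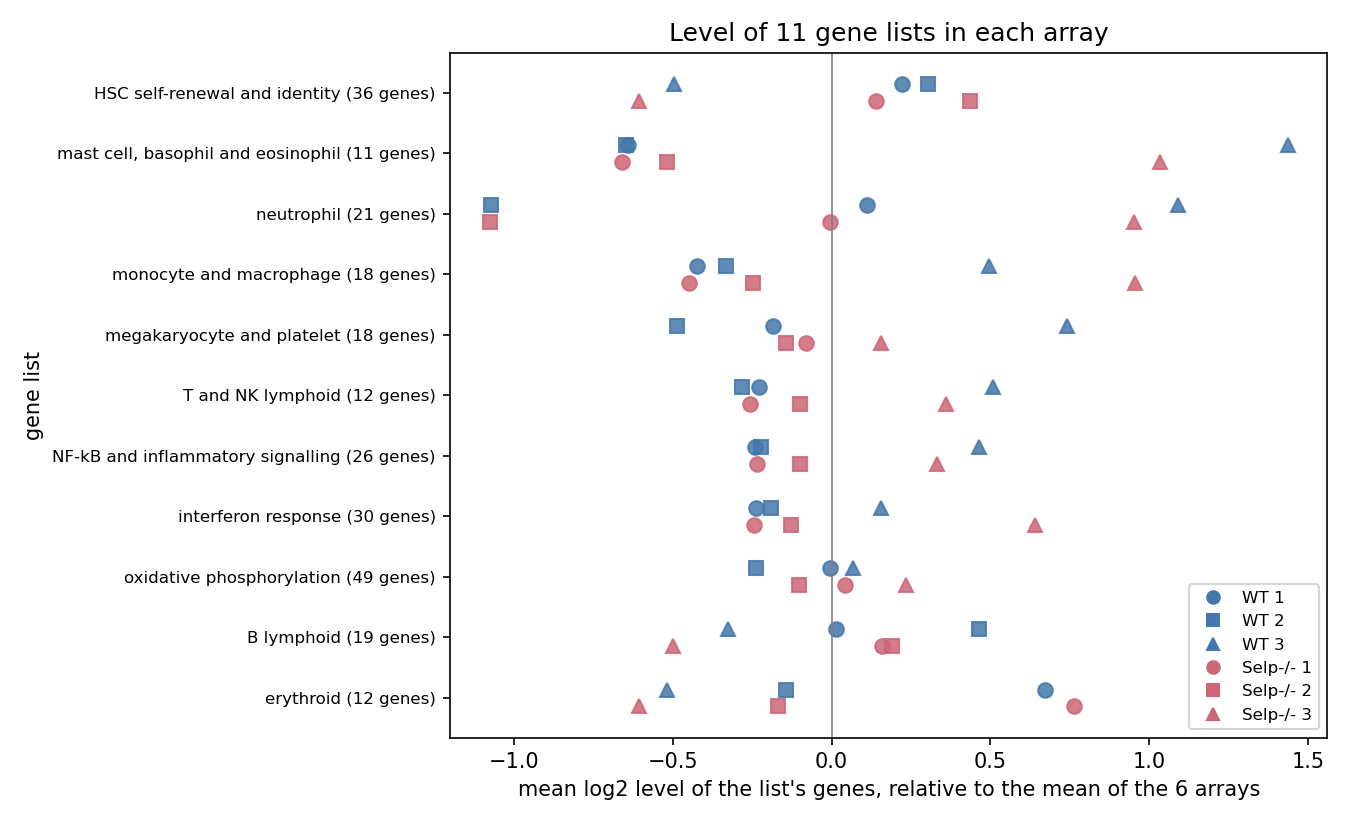
Mean log2 level of 11 gene lists in each array relative to the mean of the 6 arrays (blue WT, red Selp-/-, with circle, square and triangle for arrays 1, 2 and 3). The HSC list lies at -0.50 and -0.61 in the arrays numbered 3 and above 0 in the other 4, and the mast cell list at 1.44 and 1.03 against values below 0.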

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

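The tests of other splits of the arrays were fixed before results were seen, and the other tests here were chosen after. Of the 10 ways to split the 6 arrays in 3 and 3, 9 gave at least as many probe sets at an unadjusted p under 0.05 as the genotypes (122, highest other 3148). All 10 gave at least as many shifted lists (2, highest other 17), and 2 gave an odds ratio near Selp at least as large (2.75, highest other 2.75). Only 10 splits exist, too few for a share under 0.05. A split with 3148 such probe sets points to sample structure, here the arrays numbered 3. Among the 4 splits that part the arrays of every number, with the replicate block, the genotypes gave 630 probe sets against 745, 1227 and 475, 2 lists against 8, 10 and 6, and an odds ratio of 5.25 against 2.75, 1.61 and 1.61.

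The lower HSC genes and higher mast cell genes of the arrays numbered 3 may come from array brightness, from fewer HSC with all other cells raised alike, or from myeloid cells. Brightness was argued against, since the HSC list in unscaled values lay at -0.64 relative to all probe sets in WT. A rise of all other cells alike was argued against by the erythroid list, for the genes it covers. The erythroid list lay at -0.78 (SE over genes 0.37) in WT 3 relative to WT 1 and WT 2. In Selp-/- 3 it lay at -0.90 (SE 0.38) by the same measure. Of its 12 genes 2 lay higher in WT 3 and 1 in Selp-/- 3. Whether the sorted cells make these genes themselves was not tested. The B lymphoid list could not decide on such a rise. That list lay at -0.57 (SE over genes 0.28) in WT 3 relative to WT 1 and WT 2, and at -0.67 (SE 0.26) in Selp-/- 3 by the same measure. Of its 19 genes 4 lay higher in WT 3, Il7r at 2.24 among them. Dntt, at -3.37 in WT 3, fell with the HSC genes and may be made by the sorted cells themselves. Mast cell genes lay 2.08 higher in WT 3 by the same measure. Either mast and myeloid cells among the sorted cells or lineage entry of HSC could give that, and these data leave both open.

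The excess of low-p genes near Selp could come from sequence carried with the targeted allele or from an effect on the nearest genes. The odds ratio of 5.25 with the replicate block is that excess itself, so it leaves flanking sequence open. An effect on the nearest genes only was argued against, with an odds ratio of 6.58 for genes from 2 to 10 Mb away. Olfml2b, Ppox, Ufc1, Nit1, Cd48, Cd84 and Dcaf8 lay close together, from 6.53 to 8.03 Mb on the same side of Selp. They may not vary independently, so the strength of the excess is uncertain. Probe sets without a gene name were outside these counts.

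The higher oxidative phosphorylation genes in Selp-/- HSC could come from the level of those genes, from the arrays numbered 3, or from variation of the whole list between arrays. Their level was argued against, since the mean lay at percentile 100 of 10000 random lists matched on level, whose median was 0.022. Random genes do not move together as these genes did (estimated correlation 0.375), so the percentile is no test of chance. The arrays numbered 3 as the only source stay open, since the mean of 0.092 in the others rests on 2 pairs, at 0.049 and 0.14, for which no exact p can lie under 0.5. Variation between arrays remained open, since the list's mean spanned 0.31 among the 3 WT arrays against a difference of 0.12 between genotypes. In part that span was shared by number, the list lying at -0.0065, -0.24 and 0.069 in WT 1 to 3. It lay at 0.042, -0.10 and 0.23 in Selp-/- 1 to 3, and the differences within the numbers were 0.049, 0.14 and 0.17. With the replicate block and an estimated correlation the list still missed the threshold (camera, unadjusted p = 0.0996).

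Genes of the Y chromosome, dim and left out of the fits, stood above every WT array in Selp-/- 3. Kdm5d measured 739.5, Eif2s3y 952.5 and Uty 637.5 there, against 578.5, 597.5 and 542 in WT 3. Xist, the transcript of the inactive X, measured 398 in Selp-/- 3 and 7764, 10286 and 5010 in WT 1, WT 2 and WT 3.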

How the results depend on the processing

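The absence of single genes past the threshold held under every alternative but 1. In the arrays numbered 1 and 2 alone, 4 probe sets were called lower in Selp-/- HSC, among them Mid1 and probe set 10351197. Without adjustment, 74 probe sets lay higher and 48 lower. These counts were 271 and 230 with no filter, 37 and 18 at the 60th percentile, 30 and 9 with no normalization, 300 and 339 with array weights and 201 and 394 in the arrays numbered 1 and 2 alone. With 1 array left out their sum ran from 75 to 557, the latter without WT 3 with 179 and 378. At an adjusted or exact p of 0.05, the replicate block changed no other call than that of Cxcr2 within the neutrophil list and that of the 20 Mb window around Selp, where the odds ratio became 3.45 (Fisher's exact p = 0.00116).

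The number of gene lists shifted was 1 with no filter, 1 with the filter at the 60th percentile, 5 with no normalization, 0 with array weights, 1 in the arrays numbered 1 and 2 alone, 0 with an estimated correlation and 0 with fry. With 1 array left out it ran from 2 to 10. Without normalization the median of all probe sets stood at 0.108, and 0.103, its difference from the median with normalization, was taken off the values of that setting. The adjusted p of camera in limma for the interferon response was 0.0898 with no filter, 0.334 at the 60th percentile and 0.984 with array weights. The oxidative phosphorylation mean was 0.095 with array weights (adjusted p of camera 0.151).

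The odds ratio of the genes near Selp was 2.17 with no normalization, where the call was lost (Fisher's exact p = 0.122), 0 in a window of 2 Mb, 1.99 in one of 20 Mb and 1.46 in one of 100 places. It was 4.60 with the filter at the 60th percentile and 4.60 in the arrays numbered 1 and 2 alone, and ran from 2.75 to 5.25 with 1 array left out.

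Of 1638 values of 88 probe sets under the alternatives, 1617 kept their direction and 21 turned. Actb gave -0.13 with median centring, -0.15 with no normalization, -0.015 with array weights and -0.030 in the arrays numbered 1 and 2 alone. In those arrays alone Gata2 gave 0.075, Gp5 0.17, Siglech -0.18 and Tfrc -0.11, and with array weights Gp5 gave 0.024. With 1 array left out the log2 fold changes ran from -0.015 to 0.032 for Actb, -0.054 to 0.42 for Cavin2, -1.82 to 0.44 for Cxcr2, -0.42 to 0.23 for Gata2 and -0.35 to 0.077 for Gp5. They ran from -2.42 to 0.084 for Igkv10-96, -1.38 to 0.29 for Igkv19-93, -0.057 to 0.34 for Siglech, -0.076 to 0.65 for Slamf1 and -0.20 to 0.61 for Tfrc.

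Of 494 list shifts, 366 stayed the same, 10 were weaker, 23 stronger and 95 turned. For apoptosis and p53 targets the mean was -0.0024 with the filter at the 60th percentile. The mean of arachidonate and lipid mediators became 0.014 with a pseudocount of 1, 0.012 with a pseudocount of 64, 0.030 with no filter, 0.013 with quantile normalization and no background correction, 0.034 with median centring, 0.011 with no normalization, 0.041 with array weights and 0.053 in the arrays numbered 1 and 2 alone. For cell cycle inhibitors and quiescence the mean was 0.015 with median centring, 0.014 with array weights and 0.069 in the arrays numbered 1 and 2 alone. The mean of cytosolic ribosomal proteins became -0.0067 with no normalization and -0.024 with array weights. For endothelial the mean was 0.0078 with median centring and 0.058 in the arrays numbered 1 and 2 alone. The mean of erythroid became 0.0073 with the filter at the 60th percentile, 0.019 with median centring, 0.023 with array weights and 0.033 in the arrays numbered 1 and 2 alone. For HSC self-renewal and identity the mean was 0.0095 with median centring and 0.025 in the arrays numbered 1 and 2 alone. The mean of immediate early and handling stress became -0.036 with the filter at the 60th percentile and -0.0024 with no normalization. For mast cell the mean was 0.027 with array weights and 0.054 in the arrays numbered 1 and 2 alone. The mean of megakaryocyte and platelet became 0.10 with array weights and 0.22 in the arrays numbered 1 and 2 alone, where it was the 1 list past the threshold (adjusted p of camera 0.00279, and 0.992 with an estimated correlation). For NF-kB and inflammatory signalling the mean was 0.022 with median centring, 0.036 with array weights and 0.065 in the arrays numbered 1 and 2 alone. The mean of Notch signalling became -0.019 with the filter at the 60th percentile. For T and NK lymphoid the mean was -0.0024 with a pseudocount of 1, -0.0038 with a pseudocount of 64, -0.054 with the filter at the 60th percentile, -0.0028 with quantile normalization and no background correction and -0.012 with no normalization.

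With 1 array left out the list means ran from -0.057 to 0.12 for adhesion and homing, -0.080 to 0.11 for apoptosis and p53 targets, -0.12 to 0.17 for arachidonate and lipid mediators, -0.29 to 0.12 for B lymphoid and -0.056 to 0.17 for cell cycle G2 and M phase. The next means ran from -0.075 to 0.059 for cell cycle inhibitors and quiescence, -0.031 to 0.13 for cell cycle S phase, -0.039 to 0.073 for cytosolic ribosomal proteins, -0.023 to 0.17 for dendritic cell and -0.16 to 0.15 for endothelial. Further ranges were -0.39 to 0.33 for erythroid, -0.037 to 0.19 for glycolysis and hypoxia, -0.27 to 0.28 for HSC self-renewal and identity, -0.081 to 0.12 for immediate early and handling stress and -0.094 to 0.35 for interferon response. They were -0.64 to 0.60 for mast cell, -0.30 to 0.31 for megakaryocyte and platelet, -0.26 to 0.46 for monocyte and macrophage, -0.64 to 0.44 for neutrophil and -0.17 to 0.23 for NF-kB and inflammatory signalling. Others were -0.023 to 0.031 for Notch signalling, -0.064 to 0.17 for stromal and osteoblast, -0.18 to 0.26 for T and NK lymphoid, -0.047 to 0.049 for TGF-beta and BMP signalling and -0.048 to 0.11 for Wnt signalling. None of the pseudocounts, filters and scalings tried turned the differences of the HSC, mast cell and neutrophil lists between the arrays numbered 3 and the others. The expression of Selp was planned as a check and gave no value, since no probe set carried its name, alone or among several, in the annotation used.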

Other observations

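Tests in this part were all chosen after results were seen. Immunoglobulin genes, which mark B lineage cells, were spread over 12 tested probe sets. At an unadjusted p under 0.05 (limma) 0 lay higher and 1 lower in Selp-/- HSC, and with the replicate block 1 higher and 4 lower. Beside Igkv4-91, Igkv10-96 gave -1.08 and Igkv9-120 1.20. Probe sets of the same gene differed, with -0.62 and -0.094 for Igkv19-93 and -0.62, -0.24 and 0.14 for Ighm, and the 2 of Igha gave 0.41 each. These genes belong to a multigene family, so single values are uncertain.

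Xist and the Y chromosome genes moved against each other across the 6 arrays. Xist measured 10757 in Selp-/- 1 and 8450 in Selp-/- 2, and Eif2s3y 136 and 328. In these intensities the rank correlation of Xist with the mean of Kdm5d, Eif2s3y and Uty was -0.943 (exact permutation p = 0.0167, n = 6). On the normalized log2 scale it was -1 (exact permutation p = 0.00278), and the linear correlation -0.73 (exact permutation p = 0.0292). The sex of the mice is not given in the sources used here.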
